A study of Homo sapiens with 12 samples.

How the data were processed

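The 12 libraries came from total RNA of OCI-AML3 degron cells, prepared with a stranded mRNA kit per the labels' protocols. The authors deposited 1 table of whole-number gene counts with a column per library, keyed by Ensembl gene ID; the submitters' processing notes name STAR, featureCounts, DESeq2 and the hg38 build, with no versions. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Values of antisense or overlapping genes are therefore uncertain. Nearly identical counts on repeated rRNA gene copies left open whether such reads were counted on each copy, so counts of gene copies are uncertain too.

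The deposited counts had 78936 lines, of which 6 were broken and belonged to 2 genes, which were left out; 78930 genes were read. Symbols came from a gene name table (42177 genes) and GENCODE 29 (15568 genes), and 21185 IDs had no symbol. Coordinates are those of GENCODE 29 on GRCh38. Columns were matched to samples by the library number in each column name and in each sample's description, an inference from the labels. Groups followed the titles. The treatment label of the NTC DMSO samples reads dTAG while their titles read DMSO, the cell line labels carry running numbers although the protocol names a single line, and the meaning of NTC is not given; these points limit what the comparisons with NTC DMSO can separate.

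Counts were analysed with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr by group, which left 24064 genes and removed 0.0795% of counts; TMM factors ranged from 0.975 to 1.02. All 12 libraries entered 1 quasi-likelihood fit (1 mean per group, robust), so that they shared an estimate of spread (common biological coefficient of variation 0.0975). The 6 comparisons were tested as contrasts, with Benjamini-Hochberg adjusted p under 0.05 called. Standard errors were the absolute log2 fold change divided by the square root of the F statistic. Pairs of libraries within a group differed by more than sampling noise, so none was a copy of another. Each was entered as a replicate, although this does not show that they came from separate cultures. Totals were 30.5 M to 59.9 M counts, and precision also depends on the spread between libraries. In data simulated for dTAG mCherry against NTC DMSO on 23701 genes, the test recovered 34 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 57 of 66 changed 4-fold, and 13 of 183 calls (7.10%) were false.

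The 25 gene lists (711 entries, of which 1 was not matched) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists in a comparison, with an estimated correlation and with fry beside it. The text names NPM1; the 10 largest increases and 10 largest decreases per comparison (5 and 5 for the add-backs against NTC DMSO) among called genes with an average log2 CPM of at least 1 and groups that do not overlap, which chance gives in 10% of genes, without Y-linked genes, XIST and genes lacking a symbol; up to 3 called members per list and direction with the smallest p; any HOX or MLL complex list member; and MYC, CDKN1A, CD34, ITGAM, CD14 and MPO. A gene named for 1 comparison is also given in others, and some genes that the rule allows are not reported here.

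Expected overlaps are the product of both list sizes divided by the genes tested. Shared dTAG mCherry libraries were assessed with 20 simulations of 4 unchanged groups, drawn from negative binomial distributions with the fitted spread. The alternatives were DESeq2 1.42.0, RLE factors, library totals only, no low-count filter (at least 1 count), at least 50 counts in at least 3 libraries, adjusted p under 0.01, an absolute log2 fold change of at least 1, the 2 groups alone, the replicate number as a block, and each library left out in turn. A division of the dTAG mCherry libraries between the comparisons was added after seeing the data. Each comparison was also refitted for all 10 splits of its 6 libraries. Python 3.11.15 was used to read the table and draw figures.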

Results

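RNA was measured in OCI-AML3 degron cells, a human acute myeloid leukaemia line that carries the cytoplasmic mutant of nucleophosmin (NPM1c), here with the mutant protein fused to a tag that dTAG-13 marks for degradation. Cells were transduced with lentivirus for full-length NPM1c (dTAG FL-NPM1c), a construct that the labels call C-body null (dTAG C-body null) or mCherry alone (dTAG mCherry). At 48 hours after transduction they received 500 nM dTAG-13, and mCherry-positive cells were sorted 24 hours later. The fourth group, NTC DMSO, received the solvent. Each of the 4 groups had 3 libraries, and the 12 libraries held between 30.5 M and 59.9 M gene counts, with a median of 41.0 M. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Libraries differed within groups. The chi-square per degree of freedom of pairs of libraries was 11.7 to 37.7 within dTAG mCherry, 4.09 to 19.4 within NTC DMSO, 4.15 to 10.6 within dTAG FL-NPM1c and 3.72 to 10.9 within dTAG C-body null. Mitochondrial transcripts took 8.41%, 7.32% and 9.63% of counts in dTAG mCherry replicates 1, 2 and 3, against 6.83% to 7.63% in the other 9 libraries. On principal component 3, with 9.89% of the variance, dTAG mCherry replicate 2 lay at 15.6 while replicates 1 and 3 lay at -26.7 and -24.4. NTC DMSO replicate 3 lay at 25.2 while replicates 1 and 2 lay at -5.82 and -4.84. The residuals of dTAG mCherry replicate 2 and NTC DMSO replicate 3 correlated at 0.40, the highest value among 54 pairs of libraries from different groups.

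NPM1 itself, a nucleolar chaperone encoded on chromosome 5 (171387116 to 171411137, plus strand, GRCh38, ENSG00000181163), was the first check of the labels. Its level was 1430 ± 117 CPM (the usual unit of counts scaled by effective library total; SD, n = 3) in NTC DMSO, 1252 ± 171 in dTAG mCherry, 1651 ± 38.9 in dTAG FL-NPM1c and 1922 ± 21.7 in dTAG C-body null. Both add-back groups were higher than dTAG mCherry, by 0.40 ± 0.09 (SE) on the log2 scale with FL-NPM1c (edgeR adjusted p = 0.0073) and by 0.62 ± 0.09 with C-body null (adjusted p = 0.0029). The former call ended without FL-NPM1c replicate 1 (0.36, adjusted p = 0.064). The 2 add-back groups did not differ detectably from each other (FL-NPM1c minus C-body null -0.22 ± 0.09, adjusted p = 0.14), and dTAG mCherry did not differ detectably from NTC DMSO (-0.19 ± 0.09, adjusted p = 0.13; -0.27, adjusted p = 0.040 without dTAG mCherry replicate 3). dTAG-13 acts on protein, so the transcript level does not measure degradation, and gene counts cannot separate construct from endogenous transcripts. The processed pseudogene NPM1P26 (chromosome 10, 96560185 to 96560922) rose with the constructs, from 0.273 ± 0.088 CPM in dTAG mCherry to 7.20 ± 1.05 with FL-NPM1c and 10.7 ± 2.04 with C-body null. Its reads can be shared with NPM1, so its value is uncertain as a measure of that locus.

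**Figure D1:**
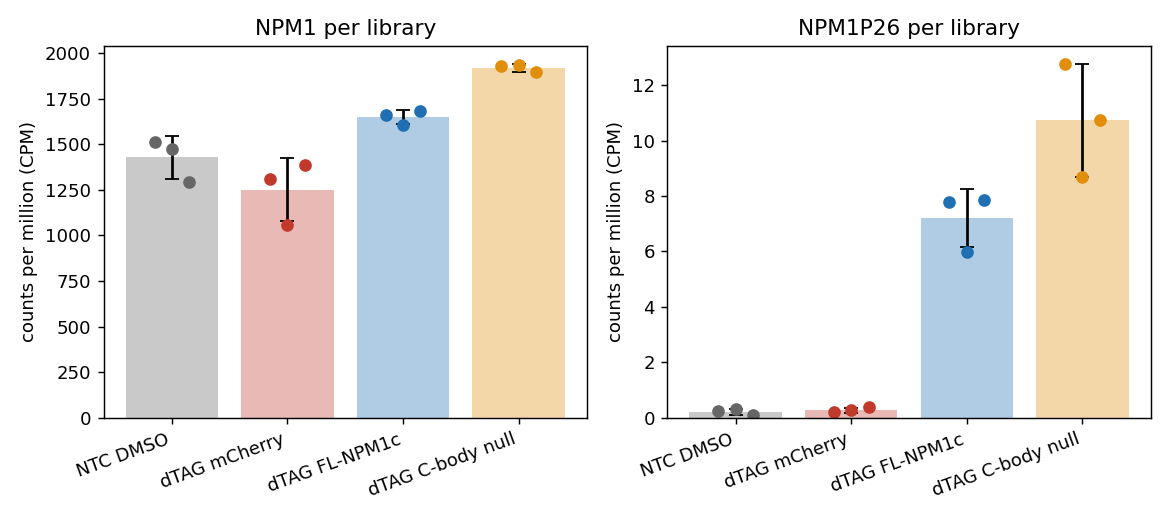
NPM1 (left) and the processed pseudogene NPM1P26 (right) in CPM; points are libraries, bars are means and error bars are SD (n = 3 per group). NPM1P26 averaged 7.20 and 10.7 CPM in the add-back groups and 0.273 CPM in dTAG mCherry.

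The comparison of dTAG mCherry with NTC DMSO addressed the loss of degron-tagged NPM1c. Genes of monocytes and macrophages rose and genes of the HOX clusters and the cell cycle fell. Of 33 tested monocyte and macrophage genes, 33 rose (33 adjusted over the list alone), with a median log2 fold change of 2.36 (camera adjusted p = 7.4e-35). The calcium-binding alarmins S100A9 and S100A8 rose by 4.98 ± 0.18 and 4.88 ± 0.21 on the log2 scale, LYZ (lysozyme) by 3.01 ± 0.08, the lipopolysaccharide co-receptor CD14 by 3.47 ± 0.24 and the integrin ITGAM by 1.97 ± 0.14. The largest increases under the naming rule were the complement genes C1QC (5.41 ± 0.45) and C3 (5.34 ± 0.26), followed by S100A9 and C1QA (4.92 ± 0.42), LILRA5, CLEC7A, TLR8 and FCN1. C3 went from 0.111 ± 0.055 to 4.59 ± 0.32 CPM, and S100A9 from 7.81 ± 0.35 to 246.9 ± 18.3 CPM.

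Of 18 tested HOX cluster and cofactor genes, 14 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 1.3e-10). HOXB9 (chromosome 17, 48621159 to 48626356) fell most under the naming rule, by 2.17 ± 0.15 on the log2 scale, from 4.94 ± 0.27 to 1.08 ± 0.19 CPM. Its neighbour HOXB8 (chromosome 17, 48611377 to 48614939) fell by 1.94 ± 0.16, HOXA13 by 1.01 ± 0.09, HOXA10 by 0.82 ± 0.07, and MEIS1, which encodes a HOX cofactor, by 0.81 ± 0.09. HOXA9 fell by 0.50 ± 0.09, from 60.6 ± 5.20 to 43.0 ± 3.32 CPM. HOXB4, HOXB5 and HOXB13 were among those that did not pass the test. Outside the clusters, the potassium channel subunit KCNMB4 (-1.78 ± 0.15), the interleukin 18 receptor genes IL18RAP (-1.64 ± 0.11) and IL18R1 (-1.28 ± 0.10), the collagen receptor DDR2 (-1.53 ± 0.12) and the peptidase DPP4 (-1.36 ± 0.11) fell.

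Growth and stress genes moved as well. Of 27 p53 target genes 25 rose (26 adjusted over the list alone; median 0.77, camera adjusted p = 3.4e-18), led by the cell cycle inhibitor CDKN1A (2.83 ± 0.09), TP53INP1 (2.27 ± 0.12) and the secreted factor GDF15 (3.48 ± 0.22). Of 37 G1/S and DNA replication genes 35 fell (37 adjusted over the list alone; median -0.58), among them CDC6 (-0.77 ± 0.08) and FEN1 (-0.72 ± 0.07). Of 35 G2/M and mitosis genes 34 fell (35 adjusted over the list alone; median -0.50), among them HJURP and BIRC5. Ribosome biogenesis factors (18 of 50 lower, 21 adjusted over the list alone; MRTO4 and FBL), MYC-responsive genes (11 of 29 lower and 1 higher; 16 and 1 adjusted over the list alone) and heat shock genes (7 of 17 lower, 10 adjusted over the list alone; FKBP4 and HSPA8) fell by smaller amounts, with medians of -0.20, -0.24 and -0.27. MYC itself was at -0.08 ± 0.07 (adjusted p = 0.46) and the granule enzyme MPO at 0.08 ± 0.20 (adjusted p = 0.82). The amino acid response list (10 lower and 4 higher of 28; 13 and 4 adjusted over the list alone) and the list of MLL complex, elongation and CRM1 genes (9 lower and 1 higher of 35; 10 and 1 adjusted over the list alone) also passed as lower. In the latter the called increase was that of ELL2 (1.11 ± 0.12), an elongation factor.

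With an estimated correlation 10 of the 14 list calls held, among them the lists above. The 4 lost were immediate early genes (13 higher and 3 lower of 29, led by BTG2 at 1.82 ± 0.10 and JUN at 1.60 ± 0.11; adjusted p = 0.075 with an estimated correlation), NF-kB and inflammatory genes (8 higher and 2 lower of 21, led by IL1B at 1.71 ± 0.11; adjusted p = 0.18), menin-MLL target genes outside the HOX clusters (8 lower and 2 higher of 21; adjusted p = 0.46) and mitochondrially encoded transcripts (4 higher of 13; adjusted p = 0.64). Adjusted over the list alone, these had 14 higher and 3 lower, 8 higher and 2 lower, 10 lower and 3 higher, and 5 higher. The NF-kB call also ended without dTAG mCherry replicate 2 (adjusted p = 0.071), and the mitochondrial call without NTC DMSO replicate 3 (0.11) and dTAG mCherry replicates 1 and 3 (0.050 and 0.34). FLT3, a receptor kinase in the menin-MLL list, rose by 0.60 ± 0.09 while CDKN2C (-0.74 ± 0.09) and SATB1 (-0.61 ± 0.07) fell. Type I interferon genes did not pass as a list (3 higher and 3 lower of 37, the same counts adjusted over the list alone; median -0.05, and -0.06 to 0.01 with each of the 6 libraries left out; mean 0.07; camera adjusted p = 0.93). TRIM22 rose by 2.15 ± 0.10 and USP18 fell by 0.99 ± 0.13 on the log2 scale.

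The lists without a passing test in this comparison were stem and progenitor markers (1 higher and 1 lower of 6), primary granule genes (5 and 1 of 14), cytosolic ribosomal proteins (0 of 79), endoplasmic reticulum stress (1 and 1 of 21), cholesterol biosynthesis (1 and 5 of 26), glycolysis and hypoxia (5 and 3 of 25) and erythroid and megakaryocyte markers (1 and 1 of 5). T and NK cell, B and plasma cell, and epithelial and fibroblast markers each had 3 tested members, too few for a test, with 0, 1 and 2 called and list means at -0.58 ± 0.69, -0.61 ± 0.14 and 0.59 ± 0.13 (SE between libraries). Counts were low. Over the 12 libraries the T and NK cell list mean lay between -0.930 and 1.58 log2 CPM, and NTC DMSO alone spanned -0.615 to 1.58. The B and plasma cell list mean lay between -1.29 and 0.824 log2 CPM. CD34, a progenitor marker, was below the count filter. Over all 24064 genes tested, 3096 were higher and 2333 lower in dTAG mCherry (edgeR, adjusted p under 0.05), and of these 1162 and 139 changed at least 2-fold. DESeq2 called 2769 higher and 2937 lower, and library totals only 3260 and 2051, so the balance of directions depends on the processing. When the fit held only the 6 libraries of these groups, 3402 genes passed. The main fit shares 1 estimate of spread over all groups. The pair of libraries that differed most was within dTAG mCherry, so that estimate may be too small for comparisons with dTAG mCherry. The NTC DMSO labels name no construct, so this comparison differs in dTAG-13 and perhaps in virus and the sort together.

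Adding back full-length NPM1c was compared with mCherry in cells that were all transduced and treated with dTAG-13. HOX genes were higher and part of the monocyte list was lower. HOXB9 was 2.22 ± 0.15 higher on the log2 scale (5.12 ± 0.44 CPM), HOXB8 1.32 ± 0.16, HOXA13 0.75 ± 0.09 and HOXA10 0.58 ± 0.07 higher. In all 11 of 18 HOX list members rose with 0 falling (12 and 0 adjusted over the list alone; median 0.57, camera adjusted p = 3.2e-08, adjusted p = 0.056 with an estimated correlation). HOXA9 (0.07 ± 0.09, adjusted p = 0.63) and MEIS1 (0.25 ± 0.09, adjusted p = 0.059) did not pass, although MEIS1 did with DESeq2 (adjusted p = 0.038) and with library totals only (adjusted p = 0.041). Of the monocyte list 16 of 33 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.35, camera adjusted p = 1.4e-07, adjusted p = 0.06 with an estimated correlation). The median was -0.56 and -0.21 without FL-NPM1c replicates 1 and 3. ITGAM fell by 2.02 ± 0.14 to 3.81 ± 0.74 CPM, the Fc receptor FCGR1A by 1.28 ± 0.08 and TLR4 by 1.04 ± 0.09, whereas CD14 (-0.35 ± 0.18, adjusted p = 0.20) did not pass and C1QA rose by 1.04 ± 0.24, a call that ended without FL-NPM1c replicate 1 (0.69, adjusted p = 0.063).

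Among the genes with the largest changes, the hyaluronan-binding protein CEMIP rose from 3.89 ± 0.71 to 23.5 ± 1.54 CPM (2.58 ± 0.14), and the relaxin receptor RXFP1 (-2.18 ± 0.17), the cytokine TNFSF14 (-2.07 ± 0.17) and the phosphatase PTPN22 (-1.95 ± 0.14) fell. Of 79 cytosolic ribosomal protein genes 42 rose (54 adjusted over the list alone), with RPL12 at 0.40 ± 0.07 and a median of 0.26 (camera adjusted p = 4.0e-12, adjusted p = 0.29 with an estimated correlation). Copies of 5.8S rRNA, whose nearly identical counts cannot be assigned to a locus, were also among the largest increases. MYC rose by 0.38 ± 0.07. The p53 list did not pass (8 higher and 2 lower of 27; 11 and 3 adjusted over the list alone; median 0.11, and -0.02 to 0.07 with each of the 6 libraries left out; camera adjusted p = 0.24), and CDKN1A was at -0.16 ± 0.09 (adjusted p = 0.21). G1/S genes rose (10 of 37, 11 adjusted over the list alone; MCM7 0.53 ± 0.10; adjusted p = 0.056 with an estimated correlation). The same applied to amino acid response genes (8 higher and 1 lower of 28, led by SLC6A9; 11 and 3 adjusted over the list alone; adjusted p = 0.06), heat shock genes (5 of 17, 6 adjusted over the list alone; adjusted p = 0.21) and menin-MLL target genes (7 of 21; 8 higher and 1 lower adjusted over the list alone; adjusted p = 0.36). Mitochondrially encoded transcripts were lower (3 of 13, 3 adjusted over the list alone; median -0.20; adjusted p = 0.68), which goes with the mitochondrial shares of dTAG mCherry replicates 1 and 3. Single libraries also ended list calls. The G1/S call ended without dTAG mCherry replicate 2 (adjusted p = 0.080). The heat shock call ended without FL-NPM1c replicates 1 and 3 (0.18 and 0.061) and dTAG mCherry replicate 2 (0.32). The mitochondrial call ended without FL-NPM1c replicate 3 (median -0.17, 0.051) and dTAG mCherry replicate 3 (-0.07, 0.14), and its median was -0.33 without dTAG mCherry replicate 2. With an estimated correlation 0 of the 8 list calls held in this comparison; without it the 8 were 6 higher and 2 lower. List means of markers of other cell types differed too, and those of B, plasma, T and NK cells rested on low counts. The list mean was higher by 0.98 ± 0.21 (SE between libraries) for epithelial and fibroblast markers (2 of 3 called higher, among them FN1 at 0.41 ± 0.09), by 0.94 ± 0.19 for B and plasma cell markers (1 of 3, SDC1 at 1.65 ± 0.14) and by 0.50 ± 0.15 for erythroid and megakaryocyte markers (2 of 5; camera adjusted p = 0.31). T and NK cell markers had 1 of 3 higher and stem and progenitor markers 2 of 6 lower. The FN1 call ended without FL-NPM1c replicate 1 and without dTAG mCherry replicate 1 (adjusted p = 0.072 and 0.083).

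In all 1823 genes were higher and 1912 lower with FL-NPM1c than with mCherry, 264 and 242 of them at least 2-fold. The count of 3735 depended on single libraries, with 6834 genes without dTAG mCherry replicate 2, 2186 and 1874 without its replicates 1 and 3, and 1834 and 1621 without FL-NPM1c replicates 1 and 2. The balance of directions changed as well, with 2100 higher and 2084 lower by DESeq2, 2503 and 1971 with no low-count filter and 3634 and 3200 without dTAG mCherry replicate 2.

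The C-body null add-back, compared with mCherry in the same way, left far fewer genes past the threshold, and HOX genes were lower. Of the 18 HOX list members 8 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.47, camera adjusted p = 5.0e-14, adjusted p = 0.0053 with an estimated correlation). HOXB8 fell by 1.60 ± 0.22 on the log2 scale to 0.330 ± 0.028 CPM, HOXB9 by 1.03 ± 0.20 to 0.535 ± 0.069 CPM, MEIS1 by 0.68 ± 0.09, HOXA13 by 0.65 ± 0.09 and HOXA9 by 0.56 ± 0.09. IL18RAP (-0.99 ± 0.12), KCNMB4 (-0.95 ± 0.18) and TP53INP2 (-0.89 ± 0.08) fell further. Monocyte genes CCR2 (0.70 ± 0.09), IRF8 (0.40 ± 0.06) and LYZ (0.45 ± 0.07) rose, as did TREM2 (0.98 ± 0.18) and TIFAB (1.05 ± 0.11). In all 3 of 33 monocyte list members passed (5 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). Copies of 7SL RNA, whose reads can be shared, were also among the largest increases. Several of these calls did not survive the loss of a library, with little change in the fold. HOXB9 had adjusted p = 0.082, 0.14 and 0.075 without C-body null replicates 1, 2 and 3 and 0.13 without dTAG mCherry replicate 1. KCNMB4 had 0.082, 0.072 and 0.12 without C-body null replicates 1, 2 and 3 and 0.057 without dTAG mCherry replicate 3. TREM2 had 0.065 and 0.055 without C-body null replicates 2 and 3 and 0.057 without dTAG mCherry replicate 1. HOXA9 and LYZ had 0.060 and 0.058 without C-body null replicate 2. HOXB8, MEIS1 and HOXA13 passed with each of the 6 libraries left out. The monocyte list call ended without dTAG mCherry replicate 2 (adjusted p = 0.063). Of the markers of other cell types 0 were called by edgeR over all genes (1 T and NK cell and 1 B and plasma cell marker lower adjusted over the list alone), while the list mean was at -0.77 ± 0.28 (SE between libraries) for T and NK cell, -0.73 ± 0.26 for B and plasma cell and -0.20 ± 0.04 for stem and progenitor markers.

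The interferon list was lower (median -0.17; 0 of 37 called over all genes and 8 lower adjusted over the list alone; camera adjusted p = 2.6e-06, adjusted p = 0.0096 with an estimated correlation), with a median of -0.26 without dTAG mCherry replicate 2. Ribosome biogenesis factors (median 0.13, 0 called and 0 adjusted over the list alone), MYC-responsive genes (median 0.10, 0 called and 4 adjusted over the list alone) and cholesterol biosynthesis genes (median 0.11, 0 called and 5 adjusted over the list alone) were higher as lists, and these 3 calls held with an estimated correlation (adjusted p = 0.0043, 0.021 and 0.021). The MYC-responsive call ended without dTAG mCherry replicate 2 (adjusted p = 0.071). The cytosolic ribosomal protein, G2/M, amino acid response and mitochondrial lists passed with 0 genes called, and were lost with an estimated correlation (adjusted p = 0.43, 0.40, 0.064 and 0.40). The amino acid response call also ended without dTAG mCherry replicate 2 (0.11), and the G2/M and mitochondrial calls without its replicate 3 (0.17 and 0.091). Neither the p53 list (median 0.08, camera adjusted p = 0.059) nor CDKN1A (0.03 ± 0.09, adjusted p = 0.92) passed, although the list did without C-body null replicate 3 and without dTAG mCherry replicate 1 (adjusted p = 0.044 and 0.039). Its median was 0.03 and 0.04 without dTAG mCherry replicates 1 and 3.

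Over all genes, 52 were higher and 91 lower with C-body null than with mCherry, 12 and 7 of them at least 2-fold. The count of 143 depended on libraries of both groups. It became 1399 (761 higher and 638 lower) without dTAG mCherry replicate 2 and 73 without dTAG mCherry replicate 1. It fell to 60, 68 and 65 without C-body null replicates 1, 2 and 3. DESeq2 called 371 genes (214 higher and 157 lower), no low-count filter 368 (174 and 194) and the fit of the 6 libraries alone 63 (30 and 33), so neither the number of changed genes nor their balance of directions is fixed by these data.

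The direct comparison of both add-backs, which uses neither dTAG mCherry nor NTC DMSO libraries in its contrast, gave 1160 genes higher and 1169 lower with FL-NPM1c than with C-body null, 311 and 195 of them at least 2-fold. HOX genes were higher with FL-NPM1c (13 of 18 called and 0 lower; 16 and 1 adjusted over the list alone; median 0.97, camera adjusted p = 4.1e-19, adjusted p = 0.0037 with an estimated correlation). HOXB9 differed by 3.25 ± 0.17 on the log2 scale, HOXB8 by 2.91 ± 0.20, HOXA13 by 1.39 ± 0.09, HOXB3 by 1.16 ± 0.09, HOXA10 by 0.96 ± 0.07, MEIS1 by 0.93 ± 0.09 and HOXA9 by 0.63 ± 0.09. CEMIP (2.68 ± 0.14), KCNMB4 (2.28 ± 0.16), ANXA2R (2.02 ± 0.13) and the proteoglycan SDC1 (1.82 ± 0.14) were also higher with FL-NPM1c.

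Monocyte genes were lower with FL-NPM1c than with C-body null in 19 of 33 members, with 0 higher (24 and 0 adjusted over the list alone; median -0.59, camera adjusted p = 4.2e-15, adjusted p = 0.015 with an estimated correlation). ITGAM differed by -1.88 ± 0.14, FCGR1A by -1.43 ± 0.08 and the chemokine receptor CCR2 by -1.45 ± 0.09, and CD14 did not pass (-0.50 ± 0.18, adjusted p = 0.097; -0.70, adjusted p = 0.039 without FL-NPM1c replicate 1). RXFP1, PTPN22, GPR84 and TNFSF14 were lower by -2.41 ± 0.17, -1.97 ± 0.14, -1.78 ± 0.12 and -1.71 ± 0.17. Interferon genes were higher with FL-NPM1c (10 higher and 2 lower of 37; 18 and 4 adjusted over the list alone; median 0.34, adjusted p = 0.036 with an estimated correlation), among them OAS3 (1.18 ± 0.14) and IFIT3 (0.77 ± 0.11). The median was 0.20 without C-body null replicate 3 and without FL-NPM1c replicate 3. G1/S genes were higher by a median of 0.11 (4 of 37, 11 adjusted over the list alone; adjusted p = 0.020 with an estimated correlation; median 0.07 without C-body null replicate 3), while the p53 list did not pass (1 higher and 1 lower of 27; camera adjusted p = 0.82). Of 3 tested B and plasma cell markers, too few for a list test, 3 were higher with FL-NPM1c, among them SDC1. Higher too were 2 of 3 epithelial and fibroblast, 1 of 3 T and NK cell and 2 of 5 erythroid and megakaryocyte markers. The menin-MLL (10 higher and 1 lower of 21, led by ADGRA3; 10 and 2 adjusted over the list alone), G2/M (5 of 35; 6 adjusted over the list alone) and cytosolic ribosomal protein (1 of 79; 1 adjusted over the list alone) lists were higher, and lost that call with an estimated correlation (adjusted p = 0.38, 0.38 and 0.68). The count of 2329 genes was 4410 (2312 higher and 2098 lower) in a fit of these 6 libraries alone. DESeq2 called 1158 higher and 1480 lower, and no low-count filter 1708 and 1368, and without C-body null replicate 3 there were 891 and 1257. It fell to 1378 and 1387 without C-body null replicates 1 and 2, and to 1511 and 1365 without FL-NPM1c replicates 1 and 2.

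**Figure D2:**
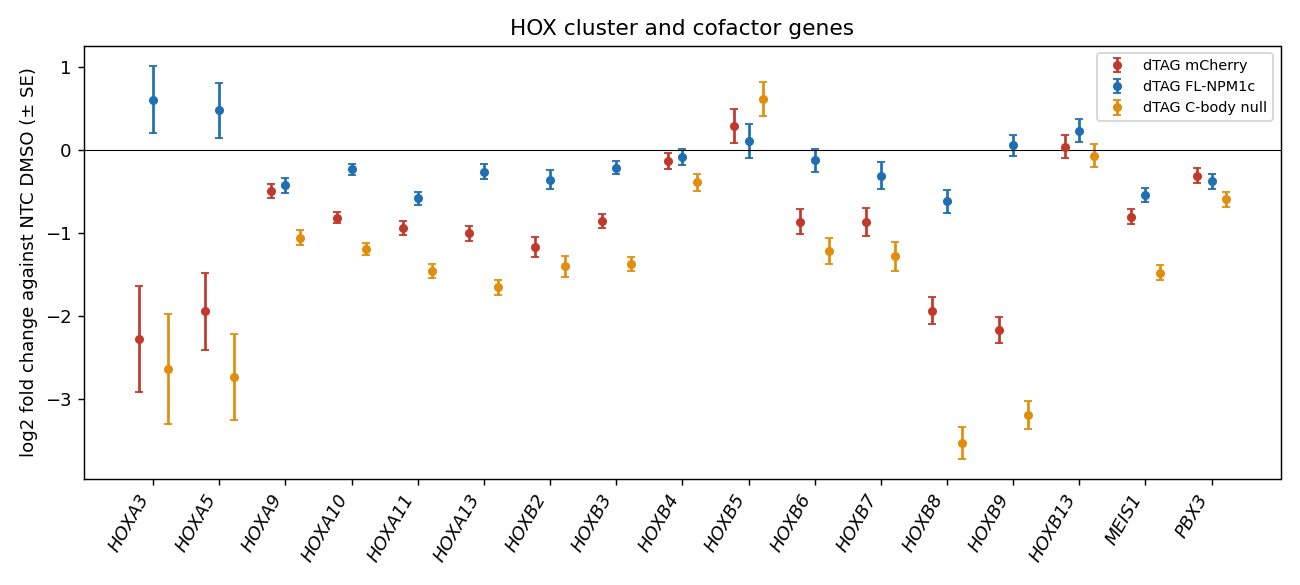
Log2 fold change of HOX cluster and cofactor genes against NTC DMSO in dTAG mCherry, dTAG FL-NPM1c and dTAG C-body null; points are edgeR estimates and bars are SE (n = 3 per group). HOXB9 lies at -2.17 with mCherry, 0.05 with FL-NPM1c and -3.20 with C-body null.

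The genes that moved with dTAG mCherry against NTC DMSO were then followed between the add-backs, a comparison that shares no library with the first. Of the 2333 genes that had fallen, 446 were higher with FL-NPM1c than with C-body null, against 112 for independent lists, and 12 were lower, against 113. Of the 3096 that had risen, 702 were lower with FL-NPM1c, against 150 for independent lists, and 86 were higher, against 149. The first overlap was 291 and 274 without C-body null replicates 1 and 2 and 297 without FL-NPM1c replicate 1. Both sets passed camera in these directions with preset (p = 4.4e-15 and 1.7e-17) and estimated correlation (p = 5.5e-05 and 1.2e-05). The correlation of the log2 fold changes was -0.34 across 24064 genes, which are not independent replicates. The covariance was -0.083, and -8.6e-05 on average in 20 simulations of unchanged groups. For the 139 genes that had fallen at least 2-fold, the median log2 fold change against NTC DMSO was -1.28 with mCherry, -0.58 with FL-NPM1c and -1.55 with C-body null. For the 1162 that had risen at least 2-fold it was 1.60, 1.28 and 1.56. The mCherry medians come from genes selected in that comparison, which draws them away from no change. The add-back medians use the same NTC DMSO libraries, so they can be drawn the same way.

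**Figure D3:**
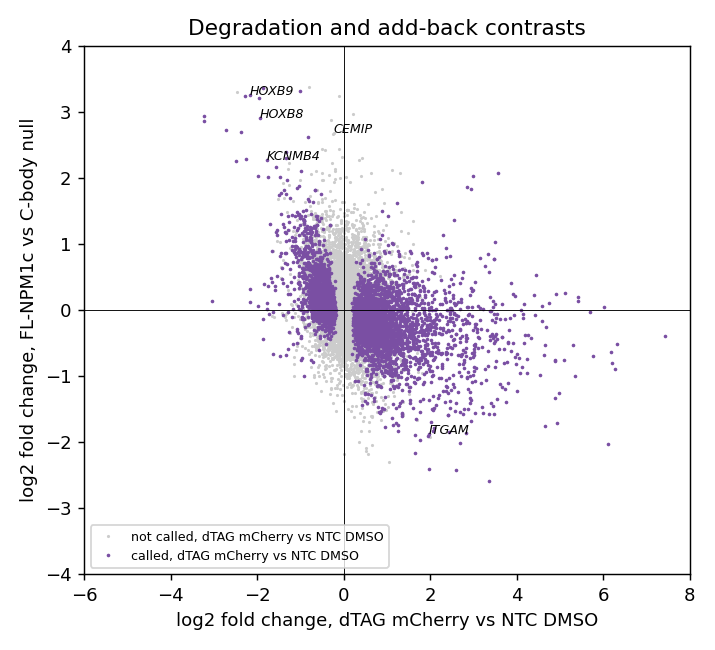
Each point is 1 of 24064 genes, with the log2 fold change of dTAG mCherry against NTC DMSO on the horizontal axis and that of FL-NPM1c against C-body null on the vertical axis; coloured points passed the first test, and 4 genes lie outside the axes. The correlation across genes is -0.34, with HOXB9 and HOXB8 at the upper left and ITGAM at the lower right.

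Against dTAG mCherry, 568 of the genes that had fallen were higher with FL-NPM1c (177 for independent lists) and 874 that had risen were lower (246 for independent lists). That makes 1442 genes moved back and 131 moved further. The 1442 became 944 and 811 without FL-NPM1c replicates 1 and 2, and 923, 2617 and 892 without dTAG mCherry replicates 1, 2 and 3. The 131 became 51 and 63 without FL-NPM1c replicates 1 and 2, 56 and 71 without dTAG mCherry replicates 1 and 3, and 78 and 202 without NTC DMSO replicates 2 and 3. With C-body null 12 genes moved back and 92 moved further, with 62 that had fallen lower again (8.82 for independent lists) and 30 that had risen higher again (6.69 for independent lists). The number moved back by C-body null was 520 without dTAG mCherry replicate 2, when 225 moved further. It was 2 and 6 without dTAG mCherry replicates 1 and 3, 2, 2 and 1 without C-body null replicates 1, 2 and 3, 4 and 7 without FL-NPM1c replicates 2 and 3, and 6 without NTC DMSO replicate 2. The number moved further was 43, 48 and 50 without C-body null replicates 1, 2 and 3 and 50 without dTAG mCherry replicate 1. These comparisons share the dTAG mCherry libraries. Simulated unchanged groups gave a correlation of -0.53 with FL-NPM1c and -0.51 with C-body null, against the observed -0.37 and -0.04. They gave 0 such genes by edgeR, which decides nothing, since genes of unchanged groups seldom pass either test. The simulated groups also had the same spread per gene. The pair of libraries that differed most was within dTAG mCherry, so the simulated shared noise may be too small. The covariance was -0.090 with FL-NPM1c against -0.027 simulated, and -0.0073 with C-body null against -0.026 simulated. In a check chosen after seeing the data, the dTAG mCherry libraries were divided, 1 to the comparison with NTC DMSO and 2 to the add-backs or the reverse, so that the comparisons shared no library. Over the 6 divisions the covariance was -0.087 to -0.030 with FL-NPM1c and 0.0086 to 0.055 with C-body null. The genes moved back by FL-NPM1c numbered 350 to 986, against 60.9 to 676 for independent lists, and the excess was smallest with replicate 2 alone against NTC DMSO (908 against 676).

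**Figure D4:**
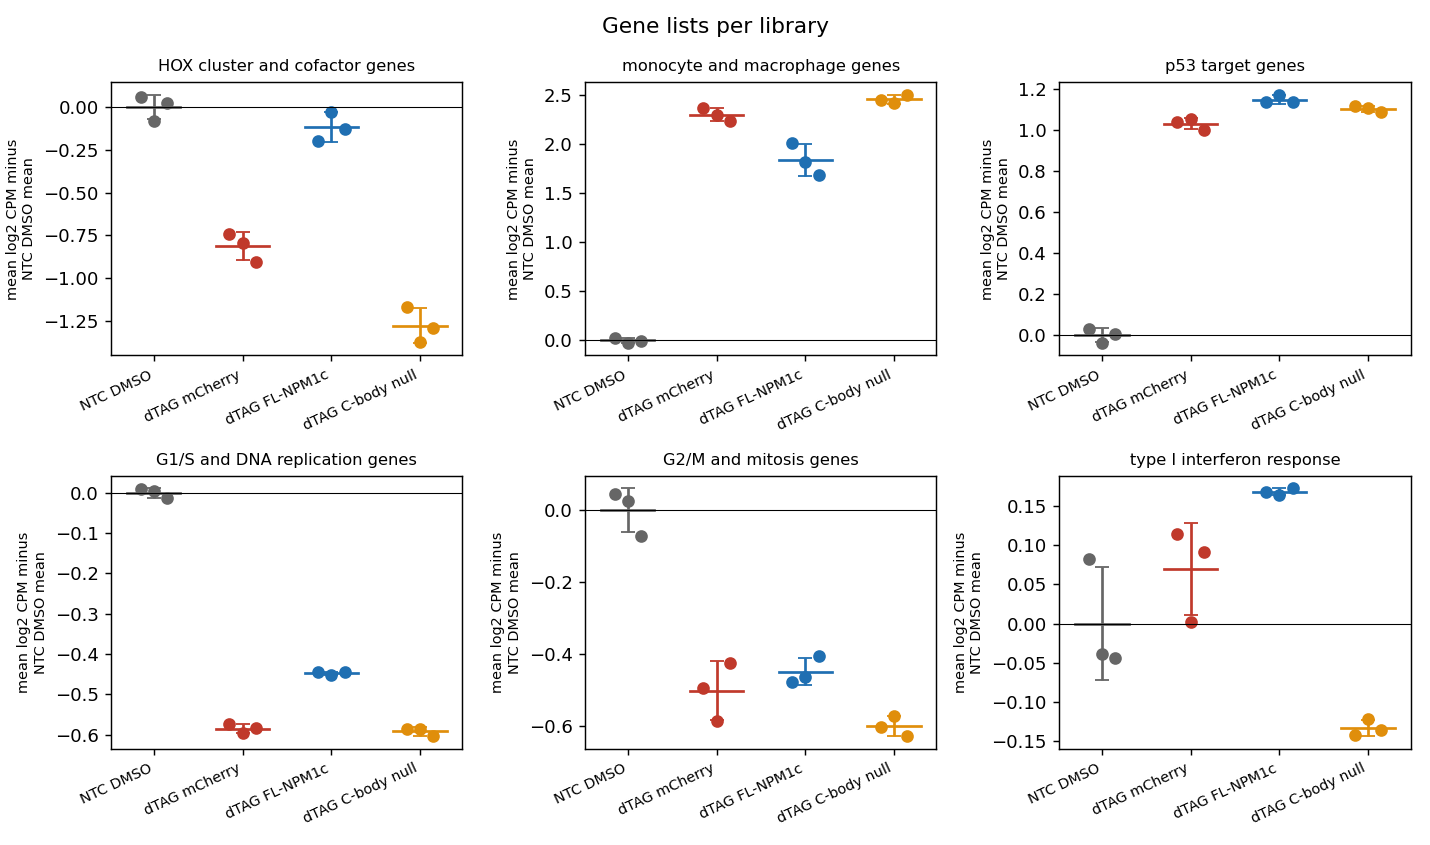
Mean log2 CPM of 6 gene lists in each library, relative to the mean of NTC DMSO; points are libraries, horizontal lines are group means and bars are SD (n = 3 per group). The HOX list mean lies 0.81 below NTC DMSO with mCherry and 1.28 below it with C-body null, and the p53 list lies 1.03, 1.15 and 1.10 above it with mCherry, FL-NPM1c and C-body null.

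Against NTC DMSO, the FL-NPM1c group kept much of the difference seen without NPM1c. Of 27 p53 target genes 22 were higher (26 adjusted over the list alone; median 0.98), with CDKN1A at 2.67 ± 0.09 and GDF15 at 4.20 ± 0.21. Of 37 G1/S genes 33 were lower (33 adjusted over the list alone; median -0.48), and of 35 G2/M genes 31 were lower (32 adjusted over the list alone; median -0.46). Monocyte genes were higher in 27 of 33 members and lower in 1 (28 and 1 adjusted over the list alone; median 1.20, camera adjusted p = 2.6e-20, adjusted p = 0.0037 with an estimated correlation). CD14 (3.12 ± 0.24), LYZ (2.87 ± 0.08) and CSF1R (3.64 ± 0.15) were higher, whereas ITGAM did not pass (-0.05 ± 0.15, adjusted p = 0.83) and FCGR1A was lower (-0.85 ± 0.08). HOXB9 was at 0.05 ± 0.13 (adjusted p = 0.80), and 8 of 18 HOX list members were lower, among them MEIS1 (-0.55 ± 0.09), HOXA9 (-0.43 ± 0.09) and HOXA11 (-0.59 ± 0.08). The list median was -0.23 (9 lower adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 47 of 79 (55 adjusted over the list alone; median 0.26; adjusted p = 0.36 with an estimated correlation). Ribosome biogenesis and MYC-responsive genes were lower (18 of 50, and 12 of 29 with 2 higher; 18, and 15 with 3 higher, adjusted over the list alone), and both calls held with an estimated correlation. Immediate early genes (17 higher and 2 lower of 29; 19 and 3 adjusted over the list alone) and the MLL complex list (10 lower of 35; 10 adjusted over the list alone) lost theirs, with adjusted p = 0.057 and 0.080. IL18RAP (-2.67 ± 0.12) and IL18R1 (-2.16 ± 0.11) had the largest decreases under the naming rule. In all 3507 genes were higher and 3205 lower; the count of 6712 was 4190 and 4302 without NTC DMSO replicates 1 and 2 and 4457 without FL-NPM1c replicate 2. DESeq2 called 3056 higher and 3751 lower. Epithelial and fibroblast markers had 2 of 3 called higher (list mean 1.57 ± 0.21) and erythroid and megakaryocyte markers 1 of 5 (1.02 ± 0.28). B and plasma cell markers had 1 of 3 higher (0.33 ± 0.19) and T and NK cell markers 1 of 3 lower (-0.58 ± 0.65), both lists with low counts.

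The C-body null group differed from NTC DMSO in 3397 higher and 2992 lower genes, with HOXB8 (-3.54 ± 0.19) and HOXB9 (-3.20 ± 0.17) the largest decreases under the naming rule. Of 18 HOX list members 15 were lower and 1, HOXB5 (0.61 ± 0.20), was higher (15 and 1 adjusted over the list alone; median -1.33, adjusted p = 0.0030 with an estimated correlation), with MEIS1 at -1.49 ± 0.09 and HOXA9 at -1.06 ± 0.09. The HOXB5 call ended with DESeq2 (adjusted p = 0.056), without NTC DMSO replicates 1 and 2 (adjusted p = 0.11 and 0.18) and without C-body null replicates 1, 2 and 3 (adjusted p = 0.060, 0.056 and 0.13). Of 33 monocyte genes 33 were higher (33 adjusted over the list alone; median 2.00), with CSF1R at 4.12 ± 0.15 and C3 at 6.20 ± 0.25. The p53 list was higher in 26 of 27 members (26 adjusted over the list alone). Of the cell cycle lists 37 of 37 G1/S and 35 of 35 G2/M genes were lower (the same counts adjusted over the list alone). Heat shock genes were lower (6 of 17; FKBP4 and HSPA8), a call that held with an estimated correlation (adjusted p = 0.039). Interferon genes were lower in 10 and higher in 4 of 37 (13 and 5 adjusted over the list alone; adjusted p = 0.079 with an estimated correlation), with IFIT3 at -0.90 ± 0.11 and TRIM22 at 2.22 ± 0.10. The other 7 list calls that ended with an estimated correlation were menin-MLL targets (adjusted p = 0.43), NF-kB (0.23), ribosome biogenesis (0.061), cytosolic ribosomal proteins (0.60), MYC-responsive (0.058), immediate early (0.12) and MLL complex genes (0.12). With 1 library left out, the NF-kB call ended without NTC DMSO replicate 2 (0.052) and C-body null replicate 3 (0.095), and the ribosome biogenesis call without NTC DMSO replicate 3 (0.057) and C-body null replicate 1 (0.059). The ribosomal protein and MLL complex calls ended without C-body null replicate 3 (0.22 and 0.054). B and plasma cell markers were lower in 3 of 3 (list mean -1.34 ± 0.26) and T and NK cell markers in 2 of 3 (-1.35 ± 0.63), both lists with low counts. Epithelial and fibroblast markers had 1 higher and 1 lower of 3 (0.91 ± 0.17) and stem and progenitor markers 1 higher and 2 lower of 6 (-0.30 ± 0.06).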

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

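The tests of HOX genes, of p53, cell cycle and interferon genes and of reads from the constructs were chosen after the results were seen; the regroupings and the test of neighbouring genes were not. A set of genes moved in opposite directions with the add-backs, each passing its own test against dTAG mCherry and the test of FL-NPM1c against C-body null. Higher with FL-NPM1c and lower with C-body null were HOXB9 (difference 3.25 on the log2 scale), HOXB8 (2.91), KCNMB4 (2.28), ANXA2R (2.02), TP53INP2 (1.85), HOXA13 (1.39), HOXB3 (1.16), HOXA10 (0.96) and HOXA11 (0.88). The reverse held for TREM2 (-1.58) and CCR2 (-1.45). In all 40 genes passed these tests in opposite directions, 31 higher with FL-NPM1c and lower with C-body null and 9 the reverse; the 11 given here belong to a list or to the genes named by the rule. In the comparisons with dTAG mCherry, single calls behind HOXB9, KCNMB4, ANXA2R, HOXA10, HOXA11 and TREM2 ended with 1 library left out: for HOXA10, adjusted p was 0.075, 0.093 and 0.091 without C-body null replicates 1, 2 and 3 and 0.050 without dTAG mCherry replicate 1; for ANXA2R 0.086 and 0.065 without C-body null replicates 1 and 2; for HOXA11 0.066 without C-body null replicate 1 and 0.078 without FL-NPM1c replicate 1. TREM2 with FL-NPM1c had 0.11 and 0.13 without FL-NPM1c replicates 2 and 3 and 0.059 and 0.11 without dTAG mCherry replicates 1 and 2.

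HOX genes were lower with C-body null than with mCherry, although both groups lacked the endogenous mutant by design. The tables argue against a single library as the whole cause, since with each of the 6 libraries left out the list median stayed at or below -0.401, and against the scaling factors, since the list mean relative to the median of all tested genes was still -0.448 ± 0.0779 (SE). A difference in differentiation state stays open: the monocyte list mean was higher by 0.156 ± 0.0463, where the HOX change predicts 1.31 ± 0.237 when scaled from mCherry against NTC DMSO but 0.308 ± 0.0894 when scaled from FL-NPM1c against mCherry, 1.51 standard errors from the measured value. That distance treats the predicted and measured changes as independent, although they share the dTAG mCherry libraries, so it decides nothing. An action of the C-body null construct itself on HOX genes also stays open. The level of either protein was not measured.

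Higher p53 target genes and lower cell cycle genes than in NTC DMSO were seen in each of the 3 dTAG groups. FL-NPM1c reversed 85.4% of the change of the HOX list mean, a proportion used without an error. List members differed: HOXB9 changed by -2.17 with mCherry and by 2.22 with FL-NPM1c, and HOXA11 by -0.95 and 0.36. An effect of NPM1c loss that FL-NPM1c reverses in that proportion of the list mean is argued against. The p53 list mean would be lower than with mCherry by 0.879, and was higher by 0.118 ± 0.0194 (SE). The cell cycle lists would be higher by 0.464, and were higher by 0.0957 ± 0.0281. A smaller reversal of the cell cycle lists stays open, since the proportion of the monocyte list (20%) gives 0.109; for the p53 list it gives -0.206, opposite to the change measured. An interferon response to the virus stays open: against NTC DMSO the interferon list mean was lower with C-body null (-0.134 ± 0.0418) and the higher of the list medians with mCherry and FL-NPM1c was 0.0633, but in each group members moved in both directions. The labels name no construct for NTC DMSO, and whether it carried one is not known. If it carried none, 0 groups have a construct without dTAG-13 or dTAG-13 without a construct. Virus, mCherry, dTAG-13 and the sort therefore cannot be told apart from the labels. An effect of NPM1c loss that the add-back does not reverse stays open too.

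NPM1P26 and NPM1P27, processed copies of NPM1, were higher in both add-back groups. Of the overlapping or nearest tested genes 0 passed as higher in both. With C-body null only 52 of all genes passed as higher than with mCherry, so this test decides little about host or neighbouring genes. The gene overlapping NPM1P26 had log2 fold changes of -0.29 with FL-NPM1c and -0.17 with C-body null. The gene overlapping NPM1P27 had -0.21 and -0.14. Nearest genes were below 0 with both, except those of NPM1P27 with FL-NPM1c (0.52 and 0.27). Transcription from a host or neighbouring gene is thus not shown but stays open. Reads from the constructs may have been counted on the copies. For NPM1P26, the lowest add-back library had 16.3 times the level of the highest dTAG mCherry or NTC DMSO library. NPM1P27 was not tested in this way. Its lowest add-back library had 17.8 CPM, and the highest of the other groups had 10.7 CPM. The group with more NPM1 above dTAG mCherry (670 CPM with C-body null, 399 with FL-NPM1c) also had more NPM1P26 above it (10.5 and 6.93 CPM). The add-back groups did not differ detectably in NPM1, so this order decides nothing. Transcription of the copies themselves stays open.

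Each comparison was repeated with its 6 libraries regrouped. In each, 1 of the 10 splits, the real one, gave as many genes as the real one, and 10 splits are too few for a share under 0.05. The real counts were 5429, 3735, 143, 2329, 6712 and 6389 for mCherry against NTC DMSO, FL-NPM1c against mCherry, C-body null against mCherry, FL-NPM1c against C-body null, and FL-NPM1c and C-body null against NTC DMSO. The highest other split gave 0 genes by edgeR in each, and 5440, 3669, 4632, 2602, 3143 and 2057 at an unadjusted p under 0.05, against 8337, 7587, 2871, 5900, 9498 and 8937 for the real split. For C-body null against mCherry that other split, which put dTAG mCherry replicates 1 and 3 with C-body null replicate 1, exceeded the real one. So did the split of dTAG mCherry replicate 2 with C-body null replicates 1 and 3 (2955 genes), which points to a structure among these libraries other than the groups.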

How the results depend on the processing

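The alternatives were fixed before the data were examined, except the division of the dTAG mCherry libraries, chosen after seeing the data. Single libraries moved the number of genes past the threshold in several comparisons; the cause was not tested, except that stricter thresholds call fewer genes by construction. For mCherry against NTC DMSO, FL-NPM1c against mCherry, C-body null against mCherry, FL-NPM1c against C-body null, FL-NPM1c against NTC DMSO and C-body null against NTC DMSO, in this order, adjusted p under 0.01 gave 3196, 1287, 71, 1169, 3647 and 3939 genes, and an absolute log2 fold change of at least 1 gave 1301, 506, 19, 506, 1282 and 1655. Leaving out each library in turn gave 4114 to 5894, 1621 to 6834, 60 to 1399, 1365 to 2148, 4190 to 7807 and 4550 to 7052 genes. The 2 groups alone gave 3402 genes for mCherry against NTC DMSO, 63 for C-body null against mCherry and 4410 for FL-NPM1c against C-body null. For C-body null against mCherry, DESeq2 gave 371, no low-count filter 368 and the replicate block 86. Replicate numbers did not pair the samples: 2 of 18 correlations between libraries of the same number were over 0.1 (range -0.31 to 0.16). Of genes that fell with mCherry, those higher with FL-NPM1c than with C-body null numbered 206 at adjusted p under 0.01, 51 at the fold minimum and 274 to 599 with a library left out; of genes that rose, those lower numbered 382, 107 and 469 to 824. Genes moved back by FL-NPM1c numbered 582, 152 and 811 to 2617, and genes moved further 42, 12 and 51 to 202, with 76 under the replicate block. Genes moved back by C-body null numbered 2 at adjusted p under 0.01, 0 at the fold minimum, 79 with DESeq2, 67 with no low-count filter, 2 under the replicate block and 1 to 520 with a library left out; genes moved further numbered 50, 8, 159 and 162 under the first 4 of these and 43 to 225 with a library left out. The division used dTAG mCherry replicates 1, 2 and 3 in turn alone against NTC DMSO, then alone against the add-backs, and the other 2 in the other comparison, with a lone library assumed to vary like the others. In this order, genes moved back by FL-NPM1c numbered 562, 908, 854, 350, 480 and 986, and moved further by it 50, 623, 48, 19, 37 and 382. Those moved back by C-body null numbered 1, 55, 2, 0, 0 and 1, and moved further by it 50, 406, 74, 5, 21 and 36. All counts moved back by FL-NPM1c were below the 1442 without the division. Some of the others were above theirs, which were 131 moved further by FL-NPM1c, and 12 moved back and 92 moved further by C-body null. The division therefore did not lower every count. With an estimated correlation 0 lists passed for FL-NPM1c against mCherry, 5 for C-body null against mCherry, 4 for FL-NPM1c against C-body null and 6 for each add-back against NTC DMSO; fry gave 16 for FL-NPM1c against NTC DMSO. Over 132 list tests the side of the threshold stayed in 100 with an estimated correlation, 106 with fry, 130 with the replicate block and 131 with library totals only. Of tests that passed in either version 0 reversed, and an estimated correlation cannot change a direction. Direction was not compared where neither version passed, and some such lists differed in direction between camera and fry. Of the tests of named genes that passed in either version, 0 reversed under DESeq2, the replicate block, library totals only or with a library left out. In this order, calls ended in 1, 6, 2 and 100 of the tests of named genes, and were gained in 12, 0, 2 and 19. The self-test recovered 34 of 67 genes changed 1.5-fold, so small changes can be missed. It changed few genes (183 calls), while mCherry against NTC DMSO had 5429 calls. More calls loosen the cutoff on unadjusted p, so the recovery rate does not carry over to that comparison.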

Other observations

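Some genes did not follow the HOX pattern. The interleukin 18 receptor genes IL18R1 and IL18RAP fell in dTAG mCherry and were lower again with either add-back, by 0.88 ± 0.11 (SE) and 1.03 ± 0.12 on the log2 scale with FL-NPM1c and by 0.86 ± 0.11 and 0.99 ± 0.12 with C-body null. The receptor kinase gene FLT3 was higher than in NTC DMSO with FL-NPM1c (0.98 ± 0.09) and C-body null (0.93 ± 0.09), and the extracellular matrix gene FN1 by 3.45 ± 0.10 and 3.02 ± 0.10. FLT3 and FN1 belonged to the menin-MLL list and to the epithelial and fibroblast markers.

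Primary granule genes did not move together. MS4A3 was higher than in NTC DMSO in the mCherry (0.98 ± 0.10), FL-NPM1c (0.72 ± 0.10) and C-body null (1.53 ± 0.10) groups. MPO passed only with C-body null among these 3 comparisons (0.92 ± 0.19), at 2.59 CPM. The list of 14 tested genes did not pass in any of the 6 comparisons, although for C-body null against NTC DMSO it did without C-body null replicates 1 and 2 (adjusted p = 0.0481 and 0.0497).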
